A study of Mus musculus with 12 samples.

How the data were processed

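RNA of 2 sorted cell types, osteoblasts and endothelial cells, of mice with and without tumor was measured on Affymetrix Mouse Gene 1.0 ST arrays, 3 per group and 12 in all. Per the labels' protocols, total RNA of 5000 cells was isolated with a Pico Pure kit, converted to cDNA, amplified by single primer isothermal amplification with a NuGEN Ovation kit and labelled with biotin. Per the submitters' processing notes the arrays were processed with the Bioconductor package affy; its version, the summary method and the probe set definition are not given in the sources used here. The deposited values are on the log2 scale, with array medians between 5.95 and 6.04, and the authors' normalization between arrays was kept. Amplification from so few cells can distort the proportions of transcripts, and log2 values near an array's floor understate fold changes.

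The table held 34760 probe sets. A platform annotation gave 1 gene symbol to 21640 of them, several symbols to 1321 and none to 11799, which are unnamed here. Symbols were updated through Entrez gene numbers in a RefSeq gene table of assembly GRCm38.p6, which matched 21553 of the single-symbol probe sets; coordinates were not used. Probe sets without exactly 1 symbol were left out of the gene tests. Of several probe sets of a gene the one with the highest mean was used, which left 19937 genes. A gene was tested if its value exceeded the array's 40th percentile of all probe sets in at least 3 of the 12 arrays, counted without regard to group, which left 14217 genes. Ly6a, Runx2 and Bglap have no single-symbol probe set and are not analysed here.

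Groups were taken from the sample titles and descriptions. A linear model with 1 coefficient per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 read the labels), with moderated statistics from eBayes and its default prior (prior degrees of freedom 2.36). The contrasts were tumor-bearing minus tumor-free in each cell type, the difference of these effects (osteoblasts minus endothelial cells), and osteoblasts minus endothelial cells within tumor-free and within tumor-bearing mice. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The arrays come from replicates that the labels call biological, without saying whether arrays of the 2 cell types share mice. The number of arrays limits the precision.

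Tested together were 36 gene lists, 21 of which describe pathways or cell states and 15 of which are markers of cell types that the gates could hold. They held 740 memberships, 617 of them among the genes tested. Each list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists and the 2 tumor contrasts, and beside it by camera with an estimated correlation and by fry. The list tests of the other 3 contrasts were chosen after the data were seen and were adjusted within each contrast. Counts adjusted over the list alone used the same p-values adjusted within the list.

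Genes were named by rule. In each tumor contrast these were up to 12 genes per direction with an adjusted p under 0.05 and arrays of the groups not overlapping; where fewer than 10 passed, also the 5 highest and 5 lowest moderated statistics. Up to 4 members with the smallest p were named from each list described, up to 5 per direction for the difference of effects, and 6 per direction for each contrast of the cell types. The genes of the sort markers and of Cdh5, Kdr, Sp7, Alpl and Col1a1 were always named.

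The steps were tested on simulated data with the real genes' means and spreads, drawn independently for each gene. For the osteoblast contrast over 14217 genes, with 200 genes changed and 50 of each size, 30%, 56%, 86% and 98% of the changes of 0.5, 1, 2 and 3 on the log2 scale were recovered, 0 with the wrong sign, and 2 unchanged genes were called. For the endothelial list tests, shifting the niche list by 0.5 gave adjusted p of 7.98e-10, 0.00777 and 0.00571 by camera with preset correlation, camera with estimated correlation and fry, and 0 other lists passed. Since the simulated genes were not correlated, this cannot show how the list tests behave in the real data, where genes can be correlated.

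The alternatives were quantile normalization, median centring, no filter, a 60th percentile filter, the mean of a gene's probe sets, eBayes with trend and robust estimation, array weights, a fit of only the groups compared, the replicate number as a block, a fold change of at least 2, camera with an estimated correlation, fry, and each array left out in turn. After the data were seen, a fit without replicate 3 of both osteoblast groups and a fit with the chondrocyte marker median of each osteoblast array as a covariate were added.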

Results

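Gene expression was measured on 12 microarrays in 2 cell types sorted from the long bones of female C57BL/6 mice, with or without growth of EO771 cells in the bones. EO771 is a mouse mammary cancer line of the same strain. Per the labels, 500000 of its cells were injected into the heart and grew in bone for about 2 weeks. Osteoblasts were sorted as CD51-positive cells without GFP, Ter119, CD45, Sca1 or CD31. Endothelial cells were sorted as Sca1- and CD31-positive cells without GFP, Ter119 or CD45. Each of the 4 groups, osteoblasts and endothelial cells of tumor-bearing and of tumor-free mice, had 3 arrays that the labels call biological replicates, each from RNA of 5000 cells. The median log2 value over all 34760 probe sets lay between 5.95 and 6.04 in the 12 arrays. After a filter on dim probe sets, 14217 genes were tested.

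In tumor-free mice the sorted cells carried the genes of their cell types. Osteoblast arrays were higher in the collagenase Mmp13 (12.16 ± 0.13 against 5.11 ± 0.25, mean log2 value ± SD, n = 3), in the matrix proteins Lum, Postn, Aspn and Tnc (log2 fold changes of 6.85, 6.54, 6.02 and 5.79) and in the protease gene Fap (5.47). Endothelial arrays were higher in the sialomucin Emcn (4.46 ± 0.27 in osteoblasts against 11.25 ± 0.08), in Il13ra2, Cd36, Ubd, the junction gene Cdh5 and Gpm6a, with osteoblast over endothelial log2 fold changes from -6.52 to -5.75. Of the genes of the sort markers, Pecam1 (CD31) differed by -4.74 and Itgav (CD51) by 1.41, and Itgav passed with a limma adjusted p of 0.0341. Itgav passed in 17 of 22 alternatives, and not without osteoblast tumor-free replicates 1 or 2 (adjusted p = 0.103 and 0.1, values of 1.29 and 1.28) or endothelial tumor-free replicate 2 (0.106, a value of 1.00). Ptprc, which encodes CD45, did not differ by limma (5.75 ± 0.61 against 5.56 ± 0.32, n = 3, adjusted p = 0.865). The bone genes Sp7, Alpl and Col1a1 were higher in osteoblasts by 2.60, 4.39 and 3.48, and the VEGF receptor gene Kdr was lower by -5.44. In tumor-bearing mice, Lum (6.89), Postn (5.86) and Fap (5.45) again stood highest, followed by the cartilage and joint genes Prg4 (5.14), Cnmd (5.04) and Mia (4.99). The lowest were Emcn (-6.39), Il13ra2 (-6.32), Gpm6a (-5.93), Cd36 (-5.86), Cdh5 (-5.77) and Ubd (-5.64).

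With limma, 1760 of the 14217 genes differed between the cell types in tumor-free mice (765 higher and 995 lower in osteoblasts) and 1503 in tumor-bearing mice (695 higher and 808 lower). The list of endothelial identity genes was lower in osteoblasts in tumor-free mice by a median of -2.79, with 21 of 24 measured members lower over all genes tested and 22 adjusted over the list alone. Its adjusted p was 5.15e-35 by camera with a preset correlation and 0.000807 with an estimated correlation. The list of osteoblast differentiation and bone matrix genes was higher by a median of 2.56, with 12 of 18 members higher and 1 lower over all genes, and 16 higher and 1 lower adjusted over the list alone (adjusted p = 4.92e-16, and 0.0193 with an estimated correlation). Markers of chondrocytes were higher in osteoblast arrays by a median of 2.41, and those of monocytes and macrophages by 0.99. Their adjusted p were 1.54e-09 and 4.04e-06 by camera, and 0.238 and 0.232 with an estimated correlation.

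In tumor-free mice the osteoblast arrays were less alike than the endothelial arrays, with pairwise correlations of the log2 values from 0.892 to 0.905 and from 0.954 to 0.963. In tumor-bearing mice the ranges overlapped, from 0.914 to 0.949 in osteoblasts and from 0.940 to 0.944 in endothelial cells. Median chondrocyte markers were 9.75, 10.14 and 7.95 in the 3 osteoblast arrays of tumor-bearing mice and 8.20, 10.17 and 8.44 in those of tumor-free mice. Pan-haematopoietic markers reached medians of 7.22 and 7.26 in replicate 3 of the tumor-bearing and of the tumor-free osteoblasts, against 6.10 to 6.55 in the other osteoblast arrays. Neutrophil markers had a median of 8.44 in replicate 3 of the tumor-free osteoblasts and of at most 6.41 in the others.

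**Figure D1:**
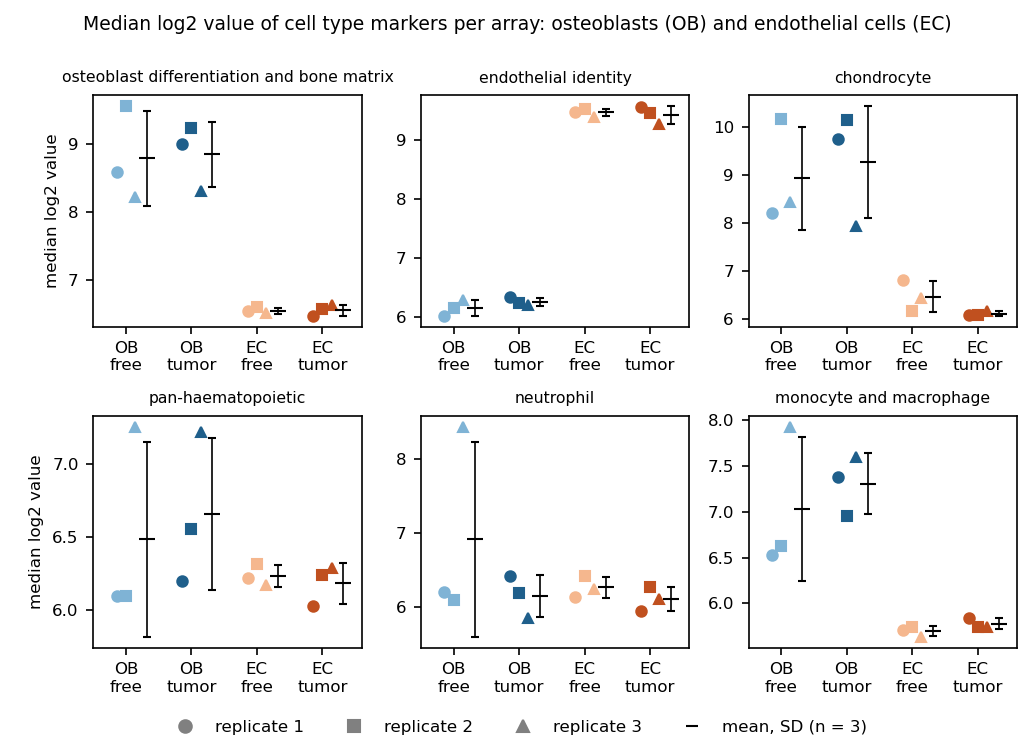
Median log2 value (vertical axis) of 6 lists of cell type markers in each of the 12 arrays, by group (horizontal axis), with replicates 1 to 3 as circles, squares and triangles and the mean and SD (n = 3) beside them. Endothelial identity genes lie between 9.27 and 9.58 in endothelial arrays, while chondrocyte and haematopoietic markers spread within the osteoblast groups, with neutrophil markers at 8.44 in 1 tumor-free array.

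The first question of the design was how osteoblasts differ between tumor-bearing and tumor-free mice. Chil1, which encodes a secreted chitinase-like protein induced in inflammation, rose from 6.37 ± 0.41 to 9.69 ± 0.51 (mean log2 value ± SD, n = 3), a 10.0-fold difference with a limma adjusted p of 0.00123. The transcription factor gene Myc rose by 1.43, S100a10, a partner of annexin A2, by 0.95, the translation initiation factor gene Eif3m by 0.99 and the RNA methyltransferase gene Ftsj1 by 1.52 on the log2 scale. The microRNA gene Mir99a fell from 8.28 ± 0.67 to 4.03 ± 0.17, the sodium channel gene Scn7a fell by 1.99 and the transcriptional adaptor gene Tada2b fell by 1.20. The adjusted p of these 7 genes lay between 0.0392 and 0.0481. In each of the 8 genes the 3 arrays of tumor-bearing mice lay on one side of the 3 tumor-free arrays. A further probe set of Eif3m had a log2 fold change of 0.53. The acute-phase gene Saa3 had a log2 fold change of 3.33 but did not pass (5.55 ± 0.85 against 8.88 ± 0.95, n = 3, limma adjusted p = 0.0747). Among the lowest values, Dera (-1.14) and Gpm6b (-0.98) did not pass either.

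In all, 8 genes passed in osteoblasts, 5 higher and 3 lower, and 1390 had an unadjusted p under 0.05, where 711 would by chance. The groups did not overlap in 2067 genes, 14.5% of those tested, where chance gives 10%. The count of 8 depended on the arrays used. It became 25 without replicate 3 of the tumor-bearing osteoblasts, 18 without replicate 3 of the tumor-free osteoblasts, 45 without both, and 2, 5 and 4 without tumor-bearing replicates 1 and 2 and tumor-free replicate 1. Leaving out an endothelial array, which changes only the shared spread, gave 1, 3 and 3 without tumor-bearing replicates 1, 2 and 3 and 2, 3 and 1 without tumor-free replicates 1, 2 and 3. A limma fit of the 6 osteoblast arrays alone called 0 genes, with 1046 at an unadjusted p under 0.05. That fit has fewer arrays, but its spread takes nothing from the endothelial arrays, which were more alike in tumor-free mice. Chil1 passed in 22 of 23 alternatives, all but that fit (adjusted p = 0.138), and the other 7 genes passed in 7 to 12 alternatives each.

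Genes of inflammation and of early stress responses were higher as lists in osteoblasts by camera with a preset correlation, and not with an estimated correlation. Of the immediate early and heat shock genes, 23 of 24 measured members had a positive log2 fold change, with a median of 0.40. Myc passed over all genes tested, and 6 members passed adjusted over the list alone. Examples were the zinc finger factor Klf6 (0.52) and the chaperone genes Hsph1 (1.27) and Hspb1 (1.55). Type I interferon response genes were positive in 21 of 25 members (median 0.42), with 0 past by limma over all genes, 8 at an unadjusted p under 0.05 and 2 adjusted over the list alone. The chemokine gene Cxcl10 had a value of 1.61 and the RNA or DNA sensors Zbp1, Ddx58 and Ifih1 had values of 0.85, 0.76 and 1.02. NF-kappaB and inflammatory cytokine genes were positive in 17 of 21 members (median 0.47), with 0 past by limma over all genes, 7 unadjusted and 1 adjusted over the list alone. Besides Saa3 they included the chemokine gene Ccl2 (1.06), the adhesion gene Icam1 (0.58) and Birc3 (0.70). The camera adjusted p of these 3 lists were 1.35e-08, 6.9e-06 and 9.64e-05. The adjusted p with an estimated correlation were 0.491, 0.491 and 0.385. Without replicate 3 of the tumor-bearing osteoblasts the interferon list no longer passed (adjusted p = 0.0653). Pan-haematopoietic markers had a median log2 fold change of -0.01 and macrophage markers of 0.09 in the same comparison, and neither list passed. Osteoclast markers had a median log2 fold change of -0.09 and a mean of 0.04, with 3 of 9 positive, and did not pass (camera adjusted p = 0.930), while their median log2 value per array was 6.96 ± 0.083 in tumor-bearing and 6.58 ± 0.176 in tumor-free mice (n = 3).

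Smaller shifts upward were seen in 5 further lists in osteoblasts. Cytosolic ribosomal proteins had a median of 0.12 with 21 of 25 positive, and unfolded protein response genes a median of 0.17 with 14 of 20 positive, including the protein disulfide isomerase gene Pdia6 (0.74) and the chaperone gene Hspa5 (0.32). Hypoxia and glycolysis genes had a median of 0.26 with 18 of 25 positive, led by the lactate dehydrogenase gene Ldha (0.82), Pfkp (0.71) and Egln3 (0.56). Cholesterol synthesis genes had a median of 0.19 with 10 of 15 positive, led by Msmo1 (1.61) and Sqle (0.92). The TGF-beta and BMP response list had a median of 0.24 with 16 of 19 positive, led by Inhba (1.91), which encodes a subunit of activin. With limma, 0 members of these 5 lists passed over all genes, and 2, 2, 3, 4 and 2 were higher at an unadjusted p under 0.05. Adjusted over the list alone, Pdia6 and Msmo1 passed, and in the TGF-beta list 1 member was higher and 1 lower. The camera adjusted p were 0.0032, 0.0116, 0.0138, 0.0451 and 0.0446 in the order given, and 0.532, 0.348, 0.656, 0.604 and 0.6 with an estimated correlation. Without replicate 3 of both osteoblast groups, the ribosomal, hypoxia and cholesterol lists had adjusted p of 0.137, 0.565 and 0.559.

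Of these 5 lists only the ribosomal proteins passed in each of the 12 fits that left out 1 array. The unfolded protein list had adjusted p of 0.119 without osteoblast tumor-bearing replicate 2 and 0.0834 without tumor-free replicate 3, and the hypoxia list 0.055 without tumor-bearing replicate 2 and 0.234 and 0.426 without tumor-free replicates 1 and 3. The TGF-beta and BMP list had 0.329 and 0.126 without osteoblast tumor-bearing replicates 1 and 2, 0.0575 and 0.172 without tumor-free replicates 1 and 3, and 0.0632 and 0.0513 without endothelial tumor-bearing replicate 2 and tumor-free replicate 1. The cholesterol list had 0.0572 and 0.24 without osteoblast tumor-bearing replicates 2 and 3, 0.312 and 0.181 without tumor-free replicates 1 and 3, and 0.0658, 0.0621 and 0.0533 without endothelial tumor-bearing replicates 2 and 3 and tumor-free replicate 1.

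Lower lists in osteoblasts were marrow stromal niche factors and markers of blood lineages. Of 18 niche factors, 16 had a negative log2 fold change (median -0.41), among them the transcription factor genes Ebf3 (-1.03) and Ebf1 (-0.89), the angiopoietin gene Angpt1 (-1.43) and the BMP antagonist gene Grem1 (-0.48). With limma, 0 of them passed over all genes, 4 were lower unadjusted and 1 passed adjusted over the list alone. Erythroid markers (median -0.41, 10 of 11 negative) included the anion exchanger gene Slc4a1 (-1.32), and 4 passed adjusted over the list alone. B cell and plasma cell markers (median -0.21, 9 of 10 negative) included the surrogate light chain gene Igll1 (-0.48), and 1 passed adjusted over the list alone. Neutrophil markers had a median of -0.73 with 13 of 15 negative, among them S100a9 (-1.03), while Anxa1 (0.81), which other cell types also express, passed upward adjusted over the list alone. With limma, 0 of these 3 marker lists' genes passed over all genes, with 4, 3 and 1 lower at an unadjusted p under 0.05. The camera adjusted p were 0.000227 for niche factors, 0.00427 for erythroid, 0.00428 for B cell and 0.00615 for neutrophil genes. With an estimated correlation the adjusted p were 0.491, 0.526, 0.268 and 0.711. The neutrophil list did not pass without replicate 3 of the tumor-free osteoblasts (adjusted p = 0.66) or replicate 3 of the tumor-bearing osteoblasts (0.0861), and the erythroid list not without the latter (0.269). Without replicate 3 of both osteoblast groups the neutrophil median was 0.00159 and the test direction turned upward (adjusted p = 0.814). Osteoblast differentiation and bone matrix genes had a median of -0.09 and did not pass (camera adjusted p = 0.561).

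**Figure D2:**
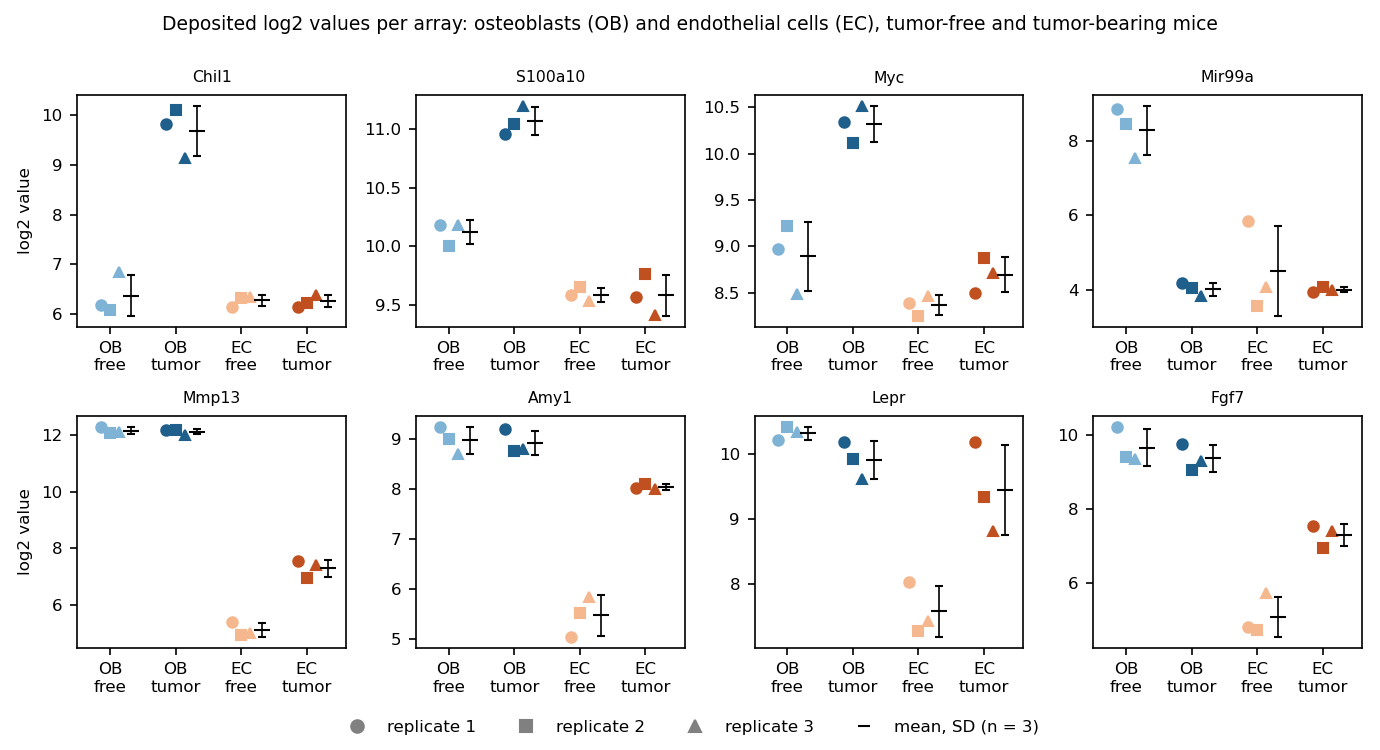
Deposited log2 values (vertical axis) of 8 genes in the 12 arrays by group (horizontal axis), with replicates as circles, squares and triangles and the mean and SD (n = 3) beside them. Chil1 lies between 9.13 and 10.11 in osteoblasts of tumor-bearing mice and at most at 6.84 elsewhere, and Amy1 at 8.0 to 8.1 in endothelial cells of tumor-bearing mice against 5.04 to 5.85 in those of tumor-free mice.

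The same question was asked of endothelial cells. There Mmp13, a collagenase gene of hypertrophic cartilage and bone, rose from 5.11 ± 0.25 to 7.29 ± 0.30 (mean log2 value ± SD, n = 3), and Amy1, which encodes an amylase, from 5.47 ± 0.41 to 8.04 ± 0.06. Both had a limma adjusted p of 0.00124, with fold changes of 4.54 and 5.95, and the 3 arrays of tumor-bearing mice lay above the 3 tumor-free arrays. Both genes were brighter still in tumor-free osteoblasts, Mmp13 at 12.16 ± 0.13 and Amy1 at 8.98 ± 0.27 (n = 3). The amylase genes are close copies, and probe sets that name several of them were not used in the test. The growth factor gene Fgf7 (5.08 ± 0.55 to 7.29 ± 0.30), Tspan14 (a log2 fold change of 0.88) and the leptin receptor gene Lepr (1.87) had the next highest test values and did not pass, nor did the lowest, Exosc7 (-0.96), Prl2c5 (-1.56), Olfr94 (-0.70), Slc35b1 (-0.73) and Gdpd1 (-1.46). With limma, 2 genes passed, both higher, and 653 had an unadjusted p under 0.05, where 711 would by chance. The groups did not overlap in 1494 genes, 10.5% of those tested, where chance gives 10%. The count of genes passing became 4 without replicate 1 and 6 without replicate 2 of the tumor-bearing endothelial cells. The 653 rest on a spread shared with the osteoblast arrays. A limma fit of the 6 endothelial arrays alone called 2 genes, 1 higher and 1 lower, with 851 at an unadjusted p under 0.05. With array weights, 1077 genes were under 0.05 unadjusted in endothelial cells and 1174 in osteoblasts. Amy1 passed in 23 of 23 alternatives, and Mmp13 in all but the fit of the 6 endothelial arrays alone (adjusted p = 0.0703).

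Marrow stromal niche factors were higher as a list in endothelial arrays of tumor-bearing mice by camera with a preset correlation, and not with an estimated correlation. Of 18 members, 17 had a positive log2 fold change with a median of 0.52. Besides Lepr they included the chemokine genes Cxcl14 (1.52) and Cxcl12 (1.06), the growth factor gene Ptn (0.92) and the stem cell factor gene Kitl (0.79). With limma, 0 members passed over all genes, 10 had an unadjusted p under 0.05 and 7 passed adjusted over the list alone. Matrix and matrix remodelling genes were positive in 29 of 37 members (median 0.24). Mmp13 was the 1 member past both over all genes and adjusted over the list alone, and the collagen gene Col8a1 (0.64), the tenascin gene Tnc (0.80) and the laminin gene Lama4 (0.95) did not pass. The camera adjusted p were 4.43e-11 and 2.5e-06, and 0.268 for both with an estimated correlation. Both lists passed in each of the 12 fits that left out 1 array.

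Markers of other stromal cells were higher as lists by camera with a preset correlation, and not with an estimated correlation or by fry. Fibroblast markers had a median of 0.12 with 12 of 14 positive, including the matrix genes Aspn (1.28) and Ogn (1.73). Adipocyte markers had a median of 0.07 with 8 of 12 positive, including the adiponectin gene Adipoq (1.62) and the lipase gene Lpl (0.72). Pericyte and smooth muscle markers had a median of 0.10 with 10 of 12 positive, including Rgs5 (1.37) and the contractile genes Myl9 (1.32) and Acta2 (1.12). With limma, 0 members of these lists passed over all genes, with 3, 4 and 3 higher unadjusted and 1, 3 and 1 adjusted over the list alone. The camera adjusted p were 0.00436, 0.00512 and 0.00552, and 0.406, 0.268 and 0.485 with an estimated correlation. The pericyte list did not pass without replicate 2 of the tumor-free endothelial cells (adjusted p = 0.053). Osteoblast differentiation and bone matrix genes had a median of 0.02 in the same arrays, with Ibsp at 1.29, and did not pass (camera adjusted p = 0.598).

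Lists of vessel, early response and proliferation genes passed by camera with a preset correlation and not with an estimated correlation. The angiogenesis and tip cell list had a median of 0.16, and 15 of 21 members were positive, including the tip cell gene Esm1 (1.71), Igfbp3 (1.33) and Cd34 (0.89). The arterial list had a median of 0.07 with 13 of 16 positive, including the calcification inhibitor gene Mgp (1.36) and the growth factor gene Vegfc (0.80). Mgp was brighter in tumor-free osteoblasts (11.72) than in endothelial cells of tumor-free (7.52) and tumor-bearing mice (8.87). Immediate early and heat shock genes had a median of 0.16 with 21 of 24 positive, led by Klf6 (0.39), Atf3 (0.82) and Egr2 (0.90). Proliferation genes were the 1 lower list, with a median of -0.19 and 27 of 34 negative. Of its 4 members with the smallest p, Tyms (-0.42) and Mki67 (-0.41) were negative and Aurkb (0.27) and Kif11 (0.64) positive. With limma, 0 members of these 4 lists passed over all genes, 4, 3 and 3 were higher and 1 lower unadjusted, and 1, 1, 0 and 0 passed adjusted over the list alone. The camera adjusted p were 0.00512, 0.0446, 0.00495 and 0.0171, and 0.268, 0.334, 0.715 and 0.715 with an estimated correlation. Endothelial identity genes had a median of 0.05, a mean of -0.02 and a downward test direction, and did not pass (camera adjusted p = 0.740).

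These 4 lists depended on single arrays. Without replicate 2 of the tumor-bearing endothelial cells the angiogenesis and immediate early lists had adjusted p of 0.116 and 0.149, and without replicate 2 of the tumor-free endothelial cells the immediate early list had 0.618 and the proliferation list 0.106. The angiogenesis list had 0.116 without tumor-free replicate 3, and the proliferation list 0.372 without tumor-bearing replicate 1 and 0.0559 without tumor-free replicate 1. The arterial list passed in 5 of the 12 fits that left out 1 array, with adjusted p of 0.0694 and 0.115 without endothelial tumor-bearing replicates 2 and 3, 0.0559 and 0.107 without endothelial tumor-free replicates 1 and 3, and 0.0629, 0.0532 and 0.064 without tumor-free osteoblast replicates 1, 2 and 3.

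In all, 12 of 36 lists passed by camera in osteoblasts (8 up, 4 down) and 9 in endothelial cells (8 up, 1 down). With an estimated correlation 0 passed in either cell type, with 3 and 5 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.268. By fry, which tests whether a list's genes move one way on balance, 1 list passed in osteoblasts, the B cell markers (adjusted p = 0.0184), and 0 in endothelial cells, with 8 and 6 unadjusted. By the fry test for change in either direction, 11 and 6 passed. The B cell markers were dim, with medians of 5.84 to 6.02 in tumor-bearing and 6.21 to 6.44 in tumor-free osteoblast arrays, where all probe sets had medians of 5.95 to 6.02.

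**Figure D3:**
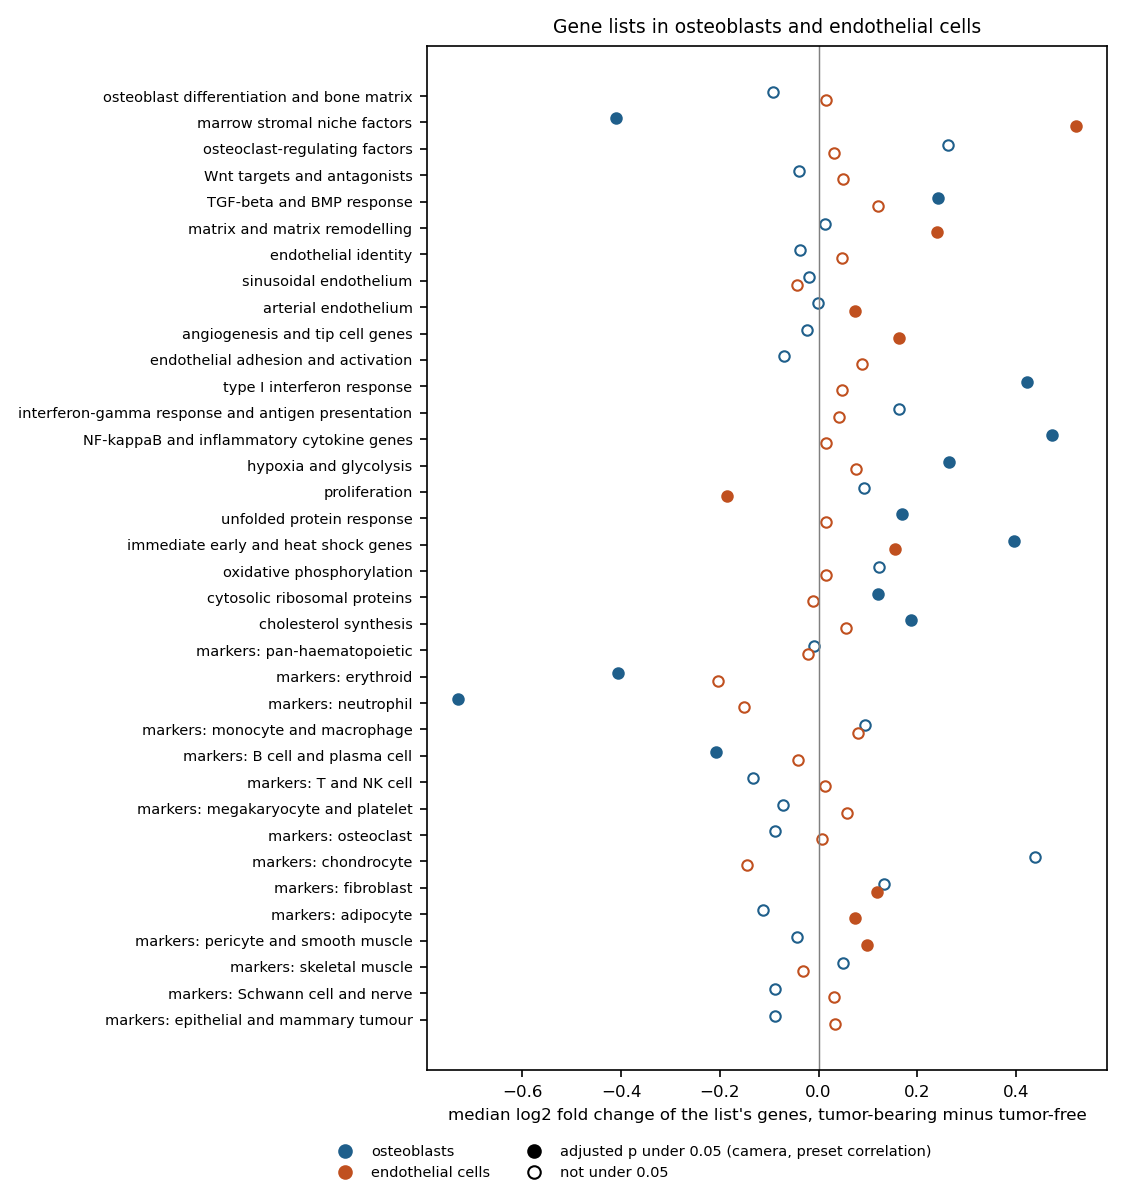
Median log2 fold change of each of the 36 gene lists, tumor-bearing minus tumor-free (horizontal axis), in osteoblasts (blue) and endothelial cells (orange), filled where the camera adjusted p with a preset correlation was under 0.05. Niche factors lie at -0.41 in osteoblasts and at 0.52 in endothelial cells, and neutrophil markers in osteoblasts lie lowest at -0.73.

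The effect of the tumor was compared between the cell types. Chil1 had a log2 fold change of 3.32 in osteoblasts and -0.02 in endothelial cells, and the difference of 3.34 passed with a limma adjusted p of 0.0179. Mmp13 (-0.04 in osteoblasts and 2.18 in endothelial cells, a difference of -2.22) and Amy1 (-0.06 and 2.57, a difference of -2.64) passed with the same adjusted p of 0.0179. Exosc7, a subunit of the RNA exosome, had values of 0.52 and -0.96, and the difference of 1.48 passed (adjusted p = 0.0472). In all, 4 genes passed in limma's test of the difference, 2 higher and 2 lower, and 920 had an unadjusted p under 0.05. Of 22 alternatives, Chil1 passed in 15, Amy1 in 14, Mmp13 in 13 and Exosc7 in 7. The count became 0 without osteoblast tumor-free replicate 1, endothelial tumor-bearing replicates 1 or 3 or endothelial tumor-free replicate 2. It became 1 without endothelial tumor-bearing replicate 2 or tumor-free replicate 3, 2 without osteoblast tumor-bearing replicates 2 or 3 or tumor-free replicate 3, and 7 without osteoblast tumor-bearing replicate 1.

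Across the 14217 genes the log2 fold changes in the 2 cell types had a Pearson r of 0.0332 and a Spearman rho of 0.0373, with genes not being independent replicates. With limma, 0 genes passed in both cell types. At an unadjusted p under 0.05, 41 genes were higher in both, where independent lists would share 21.6, 21 were lower in both (11.1), and 39 had opposite signs (31.1). The lists are not independent, since both comparisons use the same spread per gene, which can raise each of these counts. The excess therefore does not show a shared response. The niche factors had medians of opposite sign. The median over their genes of the difference of effects was -1.03, with a camera adjusted p of 1.88e-12 and of 0.202 with an estimated correlation. Among them, Angpt1 had values of -1.43 in osteoblasts and 1.44 in endothelial cells and Lepr of -0.41 and 1.87, and neither passed in either cell type or in the difference (limma adjusted p of the difference 0.38 and 0.276).

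**Figure D4:**
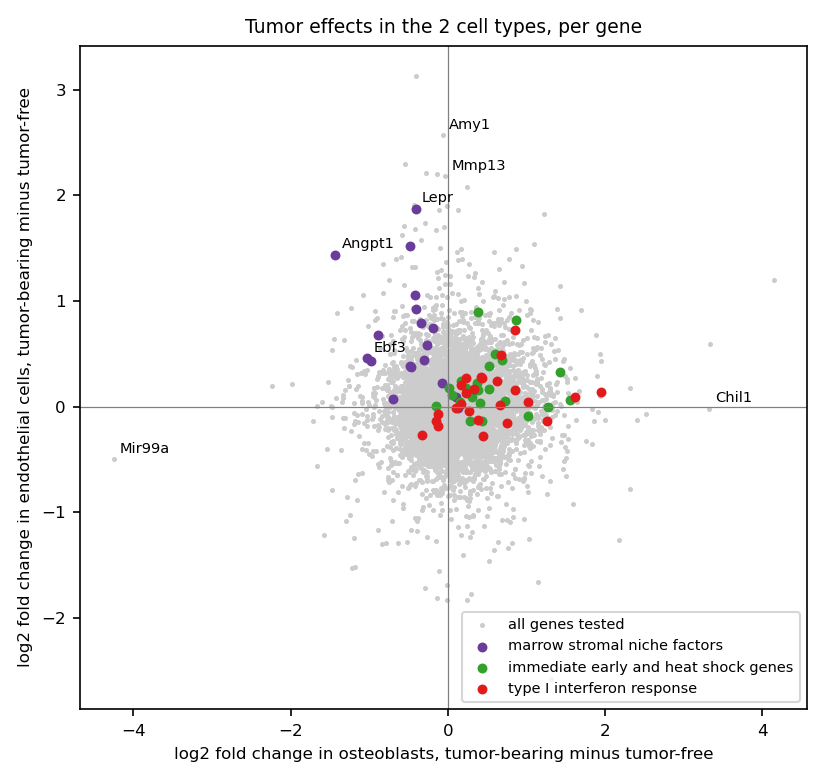
Log2 fold change, tumor-bearing minus tumor-free, of each tested gene in osteoblasts (horizontal axis) and endothelial cells (vertical axis), with 3 gene lists in colour. The points form a cloud with a Pearson r of 0.0332, in which 16 of 18 niche factors lie left of 0 and 17 of 18 above 0.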

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

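All tests of explanations in this part were chosen only after the results were seen, and so were the list tests of the difference of effects; the splits of the arrays into other groups were chosen before. In 4 genes and 8 lists the effect of the tumor differed between the cell types, as osteoblast minus endothelial log2 values. The genes were Chil1 (3.34), Exosc7 (1.48), Mmp13 (-2.22) and Amy1 (-2.64). The lists, by median, were NF-kappaB and cytokine genes (0.46, camera adjusted p = 0.00302, and 0.621 with an estimated correlation), immediate early and heat shock genes (0.184; 0.00902 and 0.737), type I interferon response genes (0.168; 0.00182 and 0.642) and ribosomal proteins (0.126; 0.0182 and 0.642). In the other direction they were niche factors (-1.03; 1.88e-12 and 0.202), pericyte markers (-0.246; 0.0492 and 0.642), adipocyte markers (-0.197; 0.00614 and 0.202) and matrix genes (-0.178; 0.0492 and 0.642). The arrays of both cell types were also split into other groups, drawn at random from 200 splits. Of 100 splits, the real one included, 8 called at least as many genes as the real one (4, highest other 14). The real one is among these 8, and chance could explain the count of genes.

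The higher niche factors in endothelial arrays (adjusted p = 4.43e-11 by camera, 0.268 with an estimated correlation, 0.147 by fry) might come from stromal cells in the CD31-positive gate. For osteoblast-lineage cells, the 12 niche genes higher in these arrays and brighter in osteoblasts would need a median of 32.2% osteoblast RNA. This share predicts a median shift of 2.39 in the 100 most osteoblast-enriched genes. The observed shift was 0.406 (SD 0.769, 74 of 100 higher, 36 at an unadjusted p under 0.05). That is too small for cells with the mean profile of the tumor-bearing osteoblast arrays to be the whole cause, though a part stays open. A subset of CD51-positive cells richer in niche genes was not tested. The 100 genes were chosen with the same tumor-free endothelial arrays that enter the shift, which can raise the observed shift. For other mesenchymal cells, 3 of 3 marker lists (fibroblast, adipocyte, pericyte) were higher by camera with a preset correlation but not with an estimated correlation (adjusted p = 0.406, 0.268 and 0.485) or by fry (0.241, 0.146 and 0.292), with Adipoq at 10.18 ± 0.57 against 8.56 ± 0.59 and Cxcl12 at 9.96 ± 0.46 against 8.90 ± 0.72 (n = 3), and this stays open. The CD31 gate should remove such cells, and in tumor-free mice 3 of 12 adipocyte and 2 of 12 pericyte markers were higher in endothelial cells than in osteoblasts, so a change within endothelial cells stays open too. Of the 10 splits of the 6 endothelial arrays, too few for a share under 0.05, the real one called 9 lists and the highest other 5.

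The rise of Mmp13 in endothelial arrays needs 2.76% of osteoblast RNA, against a median share of 2.43% over the 100 osteoblast-enriched genes with quartiles of -0.02% and 7.89%. The share of 2.76% predicts a median shift of 0.45 in the other 99 genes, where 0.40 was observed. The genes were chosen with the tumor-free endothelial arrays that also enter the shifts, which can raise the shares and the observed shifts. Single genes departed from the predicted shift, Lum with 0.03 observed and 2.10 predicted, Fap with 0.06 and 1.16 and Postn with 0.54 and 1.73. Aspn, with 1.28 and 1.38, lay close to it. These genes were chosen after their values were seen. Of the 100 genes, 26 were not higher, so a trace of osteoblast RNA stays open for Mmp13 without being shown. Amy1 needs 49.9%, above the 90th percentile of 17.9%, so RNA with the mean profile of the tumor-bearing osteoblast arrays is not a likely source on its own. Of the probe sets without a single symbol, 14 passed in endothelial cells, 3 of them higher, and 2 of these name other amylase genes (3.01 and 1.56, limma adjusted p = 0.0203 and 0.0411), which are close copies of Amy1. Of 10 splits, too few for a share under 0.05, the real one called 2 genes and the highest other 0, so only the real split reached that count.

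The immediate early, interferon and cytokine genes in osteoblasts (61 of 70 higher, median 0.43; adjusted p = 0.491, 0.491 and 0.385 with an estimated correlation) might come from other cells or from handling. Tumor cells should be removed by the GFP gate, and epithelial and mammary tumor markers gave no sign of them, with a median of -0.0891 (SD 0.245, 2 of 11 higher). These markers were dim, with medians of 5.89 to 6.08 in the osteoblast arrays. No array of EO771 cells shows that the line expresses them, so tumor cells are not excluded. Haematopoietic cells, which the CD45 and Ter119 gates should remove, remain undecided, with a pan-haematopoietic median of -0.0103 (SD 0.48, 5 of 12 higher) but, without replicate 3 of both groups, a macrophage median of 0.28 and upward calls of Lcp1, Ms4a6c and Srgn, beside pan-haematopoietic and neutrophil medians of -0.0123 and 0.00159. Stress of dissociation could act in both cell types, and the immediate early list had a camera adjusted p of 0.00495 in endothelial cells, but 0.715 with an estimated correlation, 0.634 by fry, 0.0603 with quantile normalization, and 0.149 and 0.618 without tumor-bearing or tumor-free endothelial replicate 2, so handling is neither shown nor excluded. Of 10 splits of the osteoblast arrays, too few for a share under 0.05, 2 called at least 12 lists, the real one (12) included (highest other 14).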

How the results depend on the processing

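The choices and their alternatives were made before the data were examined, except the fit without osteoblast replicate 3 of both groups and the chondrocyte covariate, tests chosen after the data were seen. The 8 genes in osteoblasts became 5 with quantile normalization, 1 with array weights, 1 with the replicate number as a block, 0 in the fit of 6 arrays and 1 to 25 with 1 array left out; without replicate 3 of both groups there were 45 (7 shared) and with the covariate 7 (5 shared). The 2 genes in endothelial cells became 2 to 6 with 1 array left out. The 4 genes of the difference of effects became 1 with the block, 8 without osteoblast replicate 3 of both groups (2 shared) and 0 to 7 with 1 array left out. The cell type counts of 1760 and 1503 became 1130 and 1000 at a fold change of at least 2, and 1241 to 1845 and 1147 to 1594 with 1 array left out. The r of 0.0332 between effects became 0.0174 with quantile normalization and 0.0133 to 0.054 with 1 array left out. The 12 lists in osteoblasts became 6 with the 60th percentile filter, 0 with an estimated correlation, 1 with fry and 10 to 14 with 1 array left out; the 9 in endothelial cells became 0, 0 and 6 to 10 in the last 3 of these. Direction turned for Ptprc between the cell types of tumor-free mice (-0.0956 to 0.507 with 1 array left out, lowest without osteoblast tumor-free replicate 3) and for Col1a2 in endothelial cells (-0.0296 to 0.242, lowest without endothelial tumor-free replicate 2). The neutrophil list in osteoblasts turned upward without replicate 3 of both groups (adjusted p = 0.814). Pairs of arrays of the same replicate number had residual correlations from -0.08 to 0.074, 0 of 18 over 0.1. Only pairs of the 2 cell types within tumor-bearing or within tumor-free mice could share mice, and these had -0.052 to 0.02. How large a correlation shared mice would give is not known, so sharing is neither shown nor excluded. Of 10 splits per contrast, too few for a share under 0.05, only the real one reached the 1760 genes (highest other 1) and the 1503 (highest other 0). The labels call the replicates biological, without stating whether they are separate mice or pools. Nor do they state what the 6 to 10 samples given for the preparation count. Whether tumor-free mice were sham injected or processed on the same days is not stated either. The p-values thus measure the spread between these samples, as 1 value per gene shared by all 4 groups. Array correlations were 0.892 to 0.905 within tumor-free osteoblasts and 0.954 to 0.963 within tumor-free endothelial cells, while the ranges overlapped in tumor-bearing mice. A shared spread can therefore be too small for the osteoblast comparison and too large for the endothelial one. How far this made the changes between settings was not tested.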

Other observations

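The tests of explanations below and the fits without osteoblast replicate 3 and with a chondrocyte covariate were chosen only after the results were seen, and the splits before. The osteoblast arrays differed in chondrocyte markers apart from the tumor. Of the 10 splits of the 6 osteoblast arrays, too few for a share under 0.05, 2 called at least 8 genes, the real one (8) included. The highest other split, with 39, set tumor-bearing replicates 1 and 2 and tumor-free replicate 2 against the rest. These 3 arrays had the highest chondrocyte marker medians (9.75, 10.14 and 10.17, against 7.95 to 8.44), which points to a structure of the samples. Without replicate 3 of both groups, 45 genes passed with limma. The osteoblast arrays left had chondrocyte medians of 9.75 and 10.14 with tumor and 8.20 and 10.17 without. Chondrocyte content was therefore not balanced in this fit, and its calls cannot be read as tumor changes alone. The following were chosen after their values were seen. The 45 genes included cartilage or tendon genes such as Tnmd (2.51), Chodl (2.33) and Cilp (1.55). Genes of blood cells among them were Lcp1 (2.04, adjusted p = 0.0231), Ms4a6c (2.28, 0.0411) and Srgn (1.43, 0.0401). Saa3 (4.30, adjusted p = 0.0101) and Inhba (2.77) passed there too. No list of tendon genes was tested.

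A hypothesis for the spread of chondrocyte markers is that the share of chondrocytes in the CD51-positive gate varied between preparations. With the chondrocyte median as a covariate, 7 genes passed in osteoblasts, 5 of them shared with the 8. The 3 lost calls kept their log2 fold changes, Ftsj1 at 1.52 (SE 0.21) and 1.49 (0.22) with the covariate, Myc at 1.43 (0.19) and 1.42 (0.20) and Tada2b at -1.20 (0.16) and -1.18 (0.17). Their adjusted p moved to 0.0667, 0.0637 and 0.064, for a cause not tested. The chondrocyte median differed little between the osteoblast groups, at 9.28 (SD 1.17) with tumor and 8.94 (SD 1.07) without. The covariate could therefore hardly move fold changes, and these calls cannot decide whether such a share made tumor differences. With the covariate 11 lists passed by camera in osteoblasts, 9 of them among those that passed without it. The TGF-beta and BMP, cholesterol and hypoxia lists no longer passed (adjusted p = 0.1075, 0.0894 and 0.0767). In tumor-free mice 10 of 15 chondrocyte markers were higher in osteoblast than in endothelial arrays, which either chondrocytes in the gate or expression by osteoblasts could give.

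A hypothesis for the higher Chil1 is an inflammatory response of CD51-positive cells to the tumor. The interferon and NF-kappaB lists that went with it had 0 members past over all genes and adjusted p of 0.491 and 0.385 with an estimated correlation, and the interferon list did not pass without osteoblast tumor-bearing replicate 3 (0.0653). The epithelial marker median of -0.0891 gave no sign of tumor cells, but no array of EO771 cells shows that the line expresses these markers. Macrophages and neutrophils, which the CD45 gate should remove, can make Chil1. In tumor-bearing replicates 1 to 3, Chil1 was 9.83, 10.11 and 9.13, with macrophage medians of 7.38, 6.95 and 7.60 and neutrophil medians of 6.41, 6.18 and 5.85. In tumor-free replicates 1 to 3, Chil1 was 6.19, 6.08 and 6.84, with macrophage medians of 6.525, 6.63 and 7.93 and neutrophil medians of 6.20, 6.095 and 8.44. These values argue against a larger share of neutrophils as the source. Macrophage markers were higher with the tumor except against tumor-free replicate 3, so a larger share of macrophages stays open. Macrophages that make more Chil1 near a tumor stay open too (pan-haematopoietic median -0.0103). Staining of sorted cells for the protein would test this.

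Niche factors had a median of -0.41 in osteoblast arrays and of 0.52 in endothelial arrays. These lists did not pass with an estimated correlation (adjusted p = 0.491 and 0.268) or by fry (0.241 and 0.147), and 0 members passed over all genes. A hypothesis is that stromal cells rich in Lepr and Cxcl12 moved between the gates or stuck to vessels when the tumor grew. The 3 of 3 mesenchymal marker lists higher in endothelial arrays, which also did not pass with an estimated correlation (0.406, 0.268 and 0.485), neither establish nor exclude it. The shift of 0.406 in osteoblast-enriched genes leaves cells with the mean profile of the tumor-bearing osteoblast arrays as a part at most. A subset of CD51-positive cells was not tested. Counting Lepr-positive cells in the CD31-positive gate would test it.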
